A study of Mus musculus with 8 samples.

How the data were processed

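Spots of 8 Visium sections of mouse liver cancer were measured, 2 for each combination of diet (Chow or MASH) and antibody (anti-PD-1 or IgG). The deposited matrices hold raw UMI counts per gene and spot, without normalization, and only for spots under tissue. Per the file headers the counts were written by Space Ranger 2.0.0, while the authors' processing notes name Space Ranger 4.0.1, Seurat 5.3.0 and R 4.4.3 and list the builds GRCm39, mm10 and GRCm38; which of these served the counts is not stated, and no genome positions are given here. The deposited enrichment tables hold a score per gene, Moran's I, with total counts that were checked to equal the matrix totals in 8 of 8 sections. Other deposited values used were spot positions, spot barcodes, gene identifiers and the image scale factors. Gene symbols follow the files, where 11 symbols occur more than once.

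Groups follow the listing in GEO. The code in a title differs from the code in the file names for 6 of 8 sections, and grouping by file-name code was tried as an alternative for each comparison of groups. Sections sharing a title letter were checked for pairing: over 7801 genes, the deviations from the group mean correlated at 0.268 for letters A and B and 0.632 for C and D, and letters also share an image scale, so pairs were not used and a block for the letter was an alternative. Replicate sections are not copies of each other, with a chi-square per degree of freedom from 87.5 to 527.

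Spots with at least 500 UMIs were kept. A spot was called hepatocyte-gene-high when its share of UMIs on 18 hepatocyte genes exceeded 3.46%, the Otsu threshold over all sections weighted equally, and these 18 genes are left out of the named genes. A section needed 50 spots in a compartment, so MASH IgG C2 is left out of fits on low spots and of the comparison of compartments. Counts were summed per section and compartment and fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, 4 group means, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05 over genes. Compartments were compared with section as a block. The 44 gene lists (577 genes, 28 of them not on the panel, Ccl19 among these) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 tested genes, and again with an estimated correlation and with fry. DESeq2 1.42.0 was the second tool. List levels are sums of CPM over the genes of a list. CPM use TMM factors, except in the comparison of compartments and by distance to the border, where they are scaled by the plain total.

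Spots were thinned to 1000 UMIs (seed 1). B-cell-marker spots had at least 2 UMIs over 14 B-cell genes and plasma-cell-marker spots at least 2 over 11 genes, and aggregates were sets of at least 3 connected spots on the grid of 6 neighbours. Shares carry exact 95% Clopper-Pearson intervals, and a share of 0 is given the limit of 3 counts. Section values were compared with two-sided exact permutation tests, 4 against 4. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

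Comparisons, lists, tests and alternatives were fixed before the data were examined, apart from those by image scale, by distance to the border, the other splits of the sections, leaving out single sections for list counts, shares of high spots and Moran's I, and list and Moran's I values by file-name code. Named genes followed a rule: genes past the threshold with a mean log2 CPM of at least 4, up to 10 in each direction (5 over whole sections); up to 4 members per list past the threshold; a fixed set of 17 genes, given as values; and, where fewer than 10 passed, the 10 smallest p. Other alternatives were upper-quartile factors, no filter, a filter of at least 50 counts in 4 sections, thinning to the shallowest section, 1000 UMIs per spot, the share threshold halved (1.73%) or doubled (6.91%), hepatocyte share as a covariate, only the groups compared, leaving out each section, 2000 UMIs after thinning, 1 or 3 UMIs per call, 5 connected spots, low spots alone and the mean in place of the median.

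The fits were tested on simulated data with the dispersion estimated from these sections and 200 changed genes, 100 by 2-fold and 100 by 4-fold. For diet in high spots 9% of genes changed 2-fold and 73% of those changed 4-fold were recovered, in low spots 32 and 70%, for anti-PD-1 in low spots 26 and 83%, within MASH 1 and 43%, and for the interaction 1 and 17%. Unchanged genes made up 9 of 91 calls for diet in high spots, 22 of 124 in low spots, 19 of 128 for anti-PD-1, 11 of 55 within MASH and 15 of 33 for the interaction. These shares exceed the 5% the threshold aims at, which bears on counts in low spots when a section is left out. Images were not analysed here.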

Results

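The data are spatial gene expression maps of mouse liver cancer sections, which hold tumour and adjacent liver in unknown proportions. The assay was Visium, which captures transcripts on a slide carrying a hexagonal grid of barcoded spots, each wide enough to hold several cells; here the transcripts were read with a panel of gene probes. Mice were fed chow or a diet labelled MASH (metabolic dysfunction-associated steatohepatitis, fatty liver with inflammation), and were given an antibody against PD-1, an inhibitory receptor of T cells, or IgG, the control antibody. Each of the 4 groups held 2 sections, so each diet and each antibody had 4. Total UMI counts (unique molecules, in M, mega) were 20.4 M and 54.6 M in Chow anti-PD-1 A1 and B1, and 19.9 M and 22.4 M in Chow IgG C1 and D1. They were 24.8 M and 22.7 M in MASH anti-PD-1 A2 and B2, and 1.04 M and 13.4 M in MASH IgG C2 and D2. The number of spots under tissue ran from 609 in MASH IgG C2 to 3453 in MASH anti-PD-1 B2, and the median UMI count per spot under tissue from 1740 in MASH IgG C2 to 15640 in Chow anti-PD-1 B1. The labels do not say whether sections came from separate animals, so p-values for single genes and for section values measure spread between sections. Camera p-values at the preset correlation set the genes of a list against the other genes, so their size reflects spread between genes.

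The letter-number code in a section's title differed from the code in its file names for 6 of the 8 sections, and groups here follow the listed titles. By the file-name codes every section listed as Chow would be anti-PD-1 and every section listed as MASH would be IgG. Each comparison by listed diet would then be a comparison by antibody. The image scale factors divided the sections by marker diameter, cut at the largest gap. The larger scale held A1, C1 and A2 (28.5 pixels) and C2 (27.8 pixels), and the smaller B1, D1, B2 and D2 (26.8 pixels). MASH IgG C2 thus lay between the others, and comparisons of scale count it as larger. As listed, each group held 1 section of each scale. With the listed groups in the model, 1652 of 14907 genes differed between the scales in liver-rich spots, 752 of them higher and 900 lower at the smaller scale. The genes that follow were chosen after their values were seen. Lower at the smaller scale were the tyrosine aminotransferase gene Tat (log2 difference in CPM, counts scaled by library size with TMM factors, of -3.42, SE 0.37, adjusted p = 0.0111), and Scd1 of fatty acid desaturation (-3.08, adjusted p = 0.0211). The macrophage scavenger receptor gene Cd163 was also lower (-3.69, adjusted p = 0.00216). The protease inhibitor gene Slpi (2.11, adjusted p = 0.00923), the T-cell gene Cd3e (1.09, adjusted p = 0.0305) and the interferon-induced chemokine gene Cxcl9 (1.96, adjusted p = 0.0256) were higher. In these spots the summed hepatocyte list, which defines the spots, also moved with scale, from 176500 to 326800 CPM at the larger and from 65740 to 121300 CPM at the smaller scale. Over whole sections 5453 of 18599 genes differed between the scales. In hepatocyte-gene-low spots, without MASH IgG C2, edgeR called 0 of 18585, with 5042 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0691. In high spots and over whole sections more genes followed image scale than the listed diet or antibody. Values with image scale as a block, and within each scale, are therefore given beside the comparisons.

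**Figure D1:**
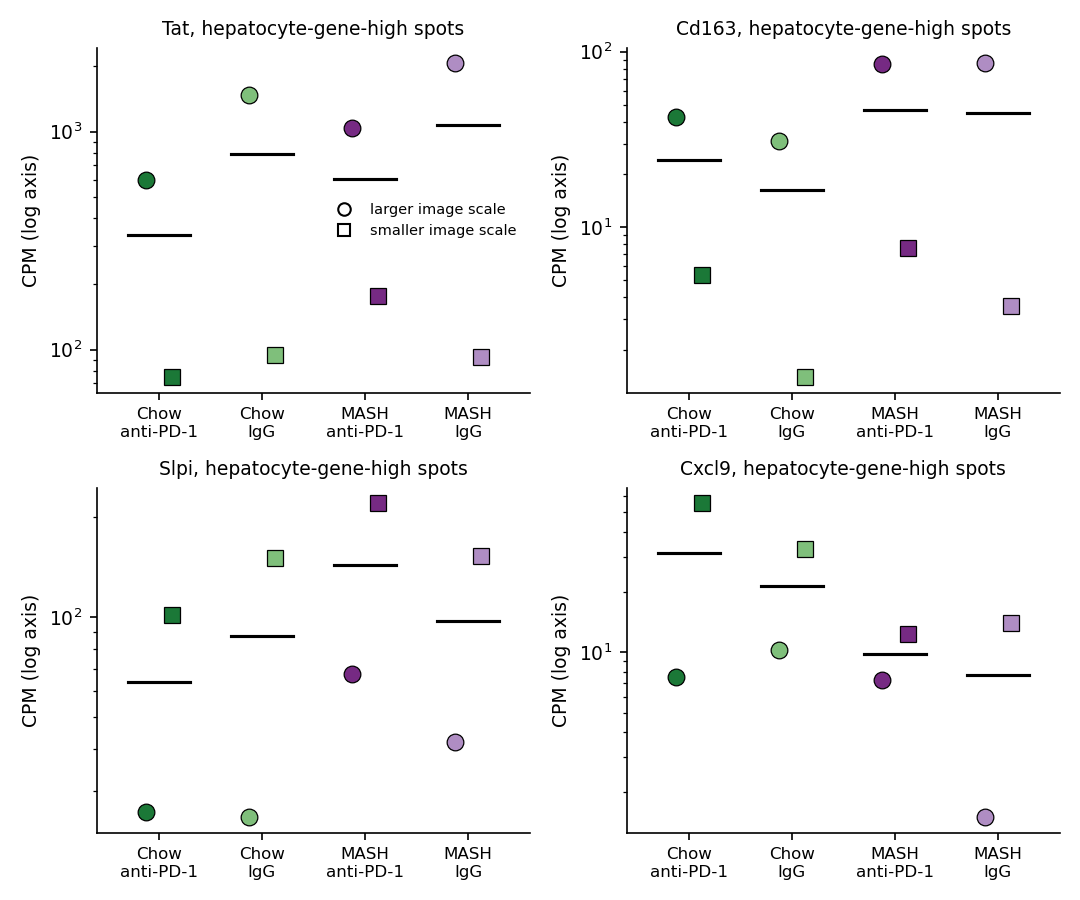
Counts scaled by library size with TMM factors (CPM, log axis) of Tat, Cd163, Slpi and Cxcl9 in the hepatocyte-gene-high spots of each section, by listed group; circles are sections of the larger and squares of the smaller image scale, and bars are group means. Tat lay between 598 and 2054 CPM at the larger scale and between 74.7 and 176 CPM at the smaller scale.

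Spots were divided into those rich in hepatocyte transcripts, called hepatocyte-gene-high (at least 3.46% of a spot's UMIs on 18 hepatocyte genes), and the rest, called hepatocyte-gene-low, to ask what liver and non-liver tissue each express. High spots carried the metabolic genes of hepatocytes, as their definition implies, so higher values of hepatocyte lists there are no independent test. CPM in this comparison are scaled by plain library size, without TMM factors. Among 13955 genes tested in the 7 sections with enough spots of both kinds, 3570 were higher in high spots and 4053 in low spots, paired within sections. Genes of phenylalanine and tyrosine breakdown were among the highest, with Hpd at 1183 ± 453 CPM in high and 85.5 ± 39.6 CPM in low spots (SD, n = 7; log2 difference 4.25, SE 0.28, adjusted p = 3.69e-06), and Tat at a log2 difference of 4.03. Of the list for phenylalanine and tyrosine catabolism, 14 of 18 genes were higher in high spots and 1 in low spots (camera adjusted p = 4.38e-06; adjusted p = 0.437 with an estimated correlation). Other genes with the largest differences were Cyp2c54 (4.33), a cytochrome P450, Tdo2 (4.15), which starts tryptophan breakdown, Gnmt (4.14), a methyl-group regulator, and Pck1 (4.14) of glucose synthesis. Kupffer cell genes were higher in high spots in 6 of 6 cases, with Clec4f at 3.87, and so were 10 of 12 endothelial genes.

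Low spots carried proliferation genes, 16 of 17 of which were higher there, among them Mki67 (-1.01; 71.6 ± 38.7 CPM in high and 174 ± 24.2 CPM in low spots) and Top2a (-0.99). They also carried Lgals3 (-1.59; 1450 ± 570 and 6057 ± 2042 CPM), Spp1 (-1.57), which encodes osteopontin, Hmga2 (-1.64), a chromatin protein of embryonic and tumour cells, and Grem1 (-1.91), a BMP antagonist. Of the interferon-γ response list 17 of 20 genes were higher in low spots (camera adjusted p = 1.82e-04; adjusted p = 0.621 with an estimated correlation), and the checkpoint ligand gene Cd274 was higher there too (-0.83). Of 17 fibrosis genes 11 were higher in low and 2 in high spots, with Col1a1 at -0.43. The stellate cell and fibroblast list went the other way, with 7 of 15 genes higher in high and 2 in low spots (median 0.52). None of 16 T-cell genes differed. Plasma cell transcripts were higher in high spots in 14 of 20 genes (camera adjusted p = 0.00330; adjusted p = 0.437 with an estimated correlation). Jchain, the joining chain of secreted antibodies, was at 1.41 (88.9 ± 92.2 and 46.3 ± 46.8 CPM), Igkc at 1.37, Mzb1 at 1.25 and Igha at 1.24. Of 13 B-cell genes 4 were higher in high spots, among them Cd79a (1.12). Not different were Ms4a1 (0.55, adjusted p = 0.144), Cd8a (-0.26, adjusted p = 0.138), Cxcl13 (-0.14, adjusted p = 0.723) and Afp (-0.15, adjusted p = 0.663). DESeq2 called 7593 genes.

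The diet comparison asked which genes differed between MASH and chow sections, first in hepatocyte-gene-low spots, where the tumour tissue would lie. Transcripts of T cells, of cytotoxic lymphocytes and of the response to interferon-γ were lower in the sections labelled MASH. These shifts rest on camera at the preset correlation, and no list was shifted with an estimated correlation or with fry. By file-name code the same split would be one of antibody, with the sections listed as Chow under anti-PD-1 and those listed as MASH under IgG. Summed over the T-cell list they were 540 ± 100 CPM in MASH and 1125 ± 414 CPM in Chow sections (SD, n = 3 and 4), and each of the 3 MASH sections lay below every Chow section. Interferon-γ response genes were at 4275 ± 896 and 7641 ± 2081 CPM, and cytotoxic lymphocyte genes at 867 ± 250 and 2052 ± 701 CPM, again with each MASH section below every Chow section. B-cell genes showed no such shift (median log2 difference 0.17, camera adjusted p = 0.951). The same held for plasma cell genes (-0.17, camera adjusted p = 0.503) and for the chemokine list of tertiary lymphoid structures (-0.14, camera adjusted p = 0.201). These structures are organised immune aggregates that form in inflamed tissue. Their list also holds genes that are not chemokines, such as Icam1, Vcam1 and Ltb, and its values are given below as those of chemokines. Summed levels of the B-cell, plasma cell and chemokine lists had lower means in MASH, with MASH and Chow sections overlapping. B-cell genes were at 91.95 ± 25.4 and 127 ± 55.7 CPM, plasma cell genes at 1624 ± 488 and 2038 ± 965 CPM, and the chemokine list at 536 ± 29.4 and 631 ± 203 CPM. Other lists moved down with the T-cell genes: neutrophil genes were at 57.9 ± 18.8 and 128 ± 27.1 CPM (median log2 difference -0.76, camera adjusted p = 0.0130), with each MASH section below every Chow section. Stellate cell and fibroblast genes were at 3266 ± 253 and 4615 ± 1715 CPM (-0.49, camera adjusted p = 0.00992). With an estimated correlation both had an adjusted p = 0.629. MASH IgG C2 had 30 low spots and is not part of this comparison.

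No single gene passed an adjusted p of 0.05 among 18585 tested with edgeR; 826 had an unadjusted p under 0.05, and DESeq2 called 103 genes, 17 higher and 86 lower in MASH. The genes with the smallest p are therefore given as values, with log2 difference MASH minus Chow. Acod1 (ENSMUSG00000022126), which makes itaconate in activated macrophages, was at -2.21 (SE 0.27; 5.48 ± 0.17 and 28.1 ± 13.7 CPM; adjusted p = 0.147). The matrix protease gene Mmp3 was at -1.80 (10.4 ± 3.47 and 36.1 ± 20.7 CPM; adjusted p = 0.147). The inducible nitric oxide synthase gene Nos2 was at -2.28 (8.62 ± 2.73 and 47.5 ± 23.3 CPM; adjusted p = 0.315) and the interferon-induced Ifitm1 at -1.34 (adjusted p = 0.315). The granzyme gene Gzmb was at -1.81 (10.9 ± 1.09 and 40.6 ± 20.6 CPM; adjusted p = 0.503). Cd274, which encodes PD-L1, was at -1.41 (91.6 ± 8.82 and 241 ± 61.6 CPM; adjusted p = 0.503), Ccl3 at -1.31, C4bp at -1.28, Traj40 at -1.74 and Fam107a at 2.30. Other genes fixed in advance were Cd8a at -1.22, Cxcl9 at -1.33, Pdcd1 at -0.54, Jchain at -0.66, Mzb1 at -0.40, Cxcl13 at -0.41 (11.7 and 10.3 CPM, so means and model differ in sign). The plasma cell list, which holds Jchain and Mzb1, reached 3372 CPM in Chow IgG C1 and at most 2186 CPM in any other section. The B-cell gene Ms4a1 was at 0.06, Cd79a at 0.20, Mki67 at -0.28 and Afp at -0.38. The phenylalanine and tyrosine enzymes Tat and Hpd were at -1.58 and -0.56, with adjusted p = 0.976 for each.

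Gene lists gave shifts where single genes did not. Adjusted over the 541 listed genes together, 0 rose and 0 fell, and the same held for every comparison by diet or antibody here (521 listed genes in high spots), so counts over the list alone carry no adjustment across lists. Adjusted over the list alone, 16 of 16 T-cell genes fell in MASH, against 0 over all genes tested, among them Trac (-1.44), Cd3e (-1.14) and Lck (-1.03). In the same way 17 of 20 interferon-γ response genes fell, such as Gbp2 (-1.12) and Cxcl10 (-1.61). So did 6 of 13 cytotoxic genes (Nkg7 at -1.35, Ccl5 at -1.33, Ifng at -1.49) and 7 of 13 checkpoint genes (Cd274, Lag3 at -0.93, Tnfrsf9 at -0.89). Others that fell were 6 of 12 type I interferon genes (Irf7 at -0.84) and 4 of 12 germinal centre genes (Fas at -0.94, Il21r at -1.02). Of the chemokine list for tertiary lymphoid structures Icam1 fell (-1.22). Camera placed the T-cell list (median -1.26, adjusted p = 1.50e-15), the interferon-γ list (-0.97, adjusted p = 5.51e-17) and the cytotoxic and checkpoint lists (-0.90 and -0.75, adjusted p = 2.38e-09 for both) below the other genes. For these lists the adjusted p = 0.432 with an estimated correlation. MHC class I (-0.65, adjusted p = 2.28e-07; adjusted p = 0.469 with an estimated correlation) and class II genes (-0.67, adjusted p = 3.53e-05; adjusted p = 0.560 with an estimated correlation) were also lower by camera, with 0 members called over the list alone. Acute phase genes, made by hepatocytes, fell in 10 of 12 cases over the list alone (median -1.30; Saa3 at -2.23, Orm1 at -2.07, Hpx at -1.34; adjusted p = 0.432 with an estimated correlation). The phenylalanine and tyrosine catabolism list was lower as well (-0.28, adjusted p = 0.00617; adjusted p = 0.469 with an estimated correlation), with no member called. Skeletal muscle genes rose in 5 of 11 cases over the list alone (median 4.18, camera adjusted p = 0.00136; adjusted p = 0.629 with an estimated correlation). Their summed level was 6332 CPM in MASH anti-PD-1 A2 and at most 20.1 CPM in any other section. In all, 25 of 44 lists were shifted, 3 up and 22 down, the hepatocyte list that defines the spots among the latter, and 0 with an estimated correlation or with fry.

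With image scale as a block the T-cell list stayed lower (median -1.20, adjusted p = 1.40e-12), and was lower within the smaller scale (-1.41, adjusted p = 5.43e-13). Within the larger scale it was at -0.71 (adjusted p = 4.42e-04), but there MASH anti-PD-1 A2 is the 1 MASH section, set against Chow anti-PD-1 A1 and Chow IgG C1, so values within the larger scale are not replicated for MASH. The interferon-γ list was at -0.94 with the block, -0.66 within the larger and -1.07 within the smaller scale. MHC class II was lower within the smaller (-0.91, adjusted p = 1.04e-04) and not within the larger scale (-0.16, adjusted p = 0.453), and MHC class I likewise (-0.86 and -0.09, the latter at an adjusted p = 0.659). Plasma cell genes went from -1.17 within the larger (adjusted p = 0.00576) to 0.42 within the smaller scale (adjusted p = 0.279). Without MASH anti-PD-1 A2 muscle genes were at 1.66 (adjusted p = 0.0175). The gene count was 0 with the block, and 78 within the larger scale, where 1 MASH section was compared. Leaving out Chow anti-PD-1 A1 gave 970 genes, 700 of them lower in MASH; leaving out Chow anti-PD-1 B1 gave 255, Chow IgG D1 12 and MASH anti-PD-1 B2 14. Grouped by file-name code, the T-cell list was not shifted (median 0.07, adjusted p = 0.366).

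**Figure D2:**
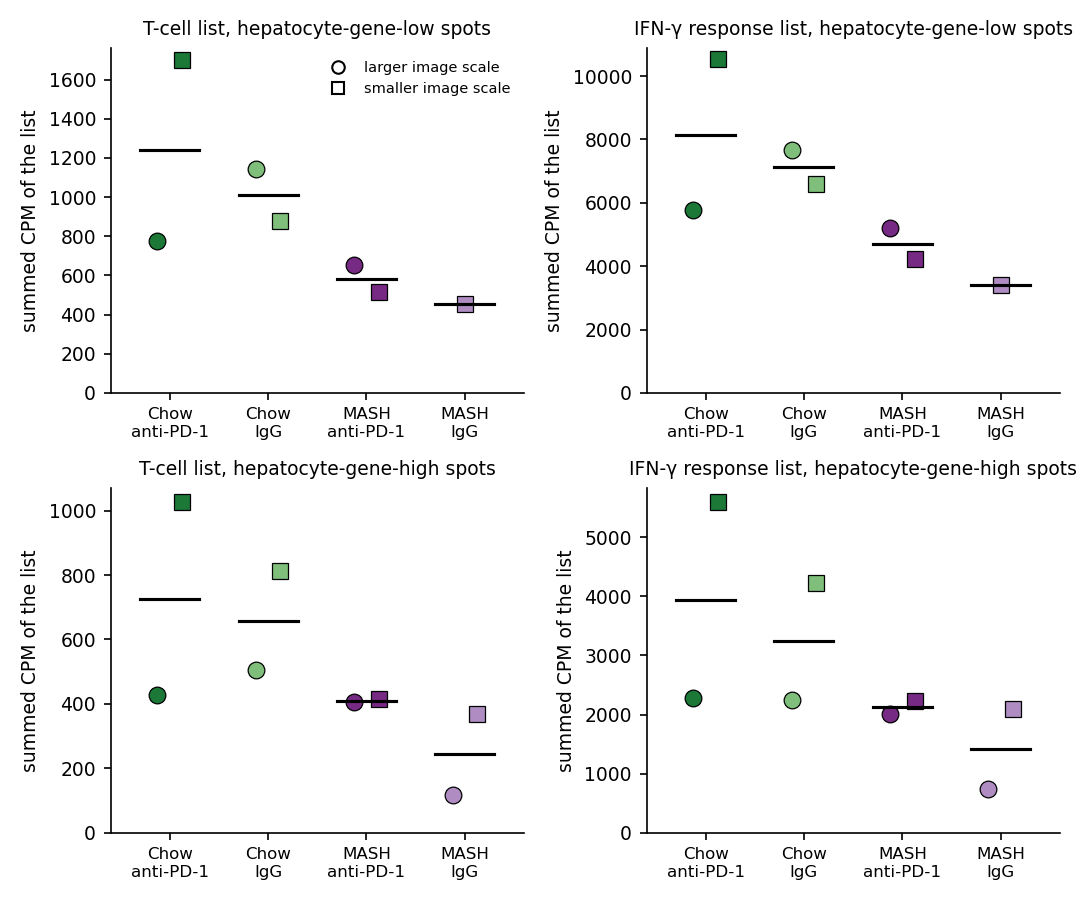
Summed CPM of the T-cell list and of the interferon-γ (IFN-γ) response list in hepatocyte-gene-low and hepatocyte-gene-high spots, 1 point per section by listed group; circles are sections of the larger and squares of the smaller image scale, and bars are group means. In low spots the T-cell list lay between 456 and 651 CPM in the MASH sections and between 777 and 1700 CPM in the Chow sections.

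In hepatocyte-gene-high spots, the comparison of diets asked the same of liver-rich spots, with 4 sections per diet. By level the T-cell and interferon-γ lists were again lower in MASH. High spots within 2 grid steps of low spots ran from 77 of 2079 in Chow IgG C1 to 874 of 971 in Chow anti-PD-1 B1. From there to over 5 steps away, T-cell genes fell from 1356 to 234 CPM of plain library size in Chow IgG C1. Admixture of low tissue is therefore not separated from expression in liver. The T-cell list was at 327 ± 141 CPM in MASH and 692 ± 278 CPM in Chow sections (SD, n = 4), and the interferon-γ list at 1768 ± 693 and 3587 ± 1628 CPM. The flavin monooxygenase gene Fmo2 was at 184 ± 84.3 and 40.0 ± 11.2 CPM, higher in 4 of 4 MASH sections than in every Chow section. The phenylalanine and tyrosine list was not shifted (median 0.25, camera adjusted p = 0.0860).

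With edgeR 0 of 14907 genes passed, 292 had an unadjusted p under 0.05, and DESeq2 called 9 (8 higher, 1 lower). Each gene named next had an adjusted p of 1.0. The log2 differences were 2.21 for Fmo2 (SE 0.40), 1.0 for Ccn2, a matricellular protein induced in fibrosis, and 0.97 for Lrrc32. Others were 1.55 for Slc16a5, 1.15 for Eppk1, 4.35 for the sulfotransferase gene Sult1e1 (44.3 ± 72.0 and 1.44 ± 0.51 CPM; 1.75 without MASH IgG C2), -1.78 for the fatty acid binding protein gene Fabp2 and -0.72 for Nop10. Tat was at 0.68 and Hpd at 0.71, with the highest values in MASH IgG C2 (2054 and 3344 CPM). In the other MASH sections they reached 1041 and 2096 CPM, against up to 1476 and 2187 CPM in Chow sections. Jchain was at -1.49 (41.1 ± 27.5 and 138 ± 167 CPM; 0.29 without Chow IgG C1), Mzb1 at -0.79 and Cd79a at 0.09 (5.61 and 6.08 CPM, so means and model differ in sign). Ms4a1 was at 0.26 and Cxcl13 at 1.30 (-0.97 without MASH IgG C2). Cd8a was at -0.92, Pdcd1 at -0.44, Cd274 at -1.24, Gzmb at -0.90, Cxcl9 at -1.36, Mki67 at -0.76 and Afp at 0.34. Camera shifted 19 of 43 lists, 7 up and 12 down, and 0 with an estimated correlation. Those down included the T-cell list (median -1.04, adjusted p = 1.05e-10), the interferon-γ list (-0.96, adjusted p = 6.28e-11; 20 of 20 genes lower). Others were MHC class I (-0.62) and class II (-0.78), type I interferon (-0.81), proliferation (-0.51) and plasma cells (-0.50, adjusted p = 0.0328). Each of these lists down had an adjusted p = 0.772 with an estimated correlation. Those up included the methionine and choline list (0.32), cholesterol synthesis (0.24), Kupffer cells (0.29) and endothelium (0.08), also with an adjusted p = 0.772 with an estimated correlation. The hepatocyte list that defines the spots is among the 7 counted as up. Adjusted over the list alone, the endothelial Vwf (0.85) and Lyve1 (1.16), Ccn2, and the muscle gene Tnnc2 rose, and no T-cell or interferon-γ gene fell. The median of the chemokine list for tertiary lymphoid structures was 0.15, while camera placed it down (adjusted p = 0.438).

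The T-cell list was lower with image scale as a block (-1.21, adjusted p = 2.75e-12) and within the larger (-1.16) and smaller scale (-1.23). Plasma cell genes turned from -1.60 within the larger (adjusted p = 2.34e-06) to 0.40 within the smaller scale (adjusted p = 0.0522). Without the shallow section MASH IgG C2, 12 lists were shifted in place of 19, and plasma cell genes were at -0.18 (adjusted p = 0.270). Grouped by file-name code, 228 genes differed by diet and both lists turned upward (T-cell list 1.16, adjusted p = 0.00106; interferon-γ list 1.08, adjusted p = 1.28e-05).

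Over whole sections the diets were compared without dividing spots, so tissue composition and expression are mixed. T-cell genes were lower in MASH, at 372 ± 146 CPM against 810 ± 281 CPM (SD, n = 4). Adjusted over the list alone 14 of 16 fell, among them Trac (33.5 ± 16.4 and 83.04 ± 27.8 CPM), Cd3e and Cd8b1. Gzmb was at 8.54 ± 0.82 and 22.4 ± 5.92 CPM, lower in 4 of 4 MASH sections than in every Chow section, and fell over the list alone together with Nkg7 and Gzmk. Muscle genes rose in 10 of 11 cases over the list alone, with a summed level of 3517 CPM in MASH anti-PD-1 A2 and at most 17.3 CPM elsewhere. No gene of 18599 passed with edgeR, 401 had an unadjusted p under 0.05 and DESeq2 called 12 (8 higher, 4 lower). The smallest adjusted p was that of Mmp3 (-1.82, SE 0.22, adjusted p = 0.686); Sfrp1 (-1.74), Icam1 (-0.96), Ms4a4b (-1.26), Fabp2 (-2.38), Fam107a (3.44; 1.89 without MASH IgG C2), Ddit4 (1.64) and Eppk1 (1.26) each had an adjusted p of 0.999. Jchain was at -1.96 (29.0 ± 22.3 and 127 ± 160 CPM; -0.39 without Chow anti-PD-1 A1 and -0.02 without Chow IgG C1), Cd274 at -1.35, Cd8a at -1.06, Tat at 0.23 and Hpd at 0.31. The phenylalanine and tyrosine list was at 11240 CPM in MASH IgG C2 and at most 3229 CPM in the other MASH sections, so values of its genes can rest on that section. Camera shifted 22 of 44 lists, 3 up and 19 down, led by T cells (median -1.22, adjusted p = 2.02e-19) and interferon-γ response (-0.94, adjusted p = 1.91e-17), both with an adjusted p = 0.700 with an estimated correlation. Plasma cell genes were lower too (-0.51, adjusted p = 0.00505; adjusted p = 0.700 with an estimated correlation). With image scale as a block the T-cell and interferon-γ lists were at -1.42 and -0.96, within the larger scale at -1.37 and -0.90, and within the smaller scale at -1.43 and -1.11. Plasma cell genes were at -0.65 with the block (adjusted p = 0.00521), -1.50 within the larger (adjusted p = 5.11e-08) and 0.41 within the smaller scale (adjusted p = 0.338). Leaving out MASH anti-PD-1 B2 gave 3 genes.

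The antibody comparison asked what anti-PD-1 changed against IgG. In hepatocyte-gene-low spots, no gene of 18585 passed with edgeR, 748 had an unadjusted p under 0.05 and DESeq2 called 31 (24 higher, 7 lower). Genes with higher values under anti-PD-1 were Txnip, an inhibitor of thioredoxin (307 ± 95.2 CPM against 99.7 ± 25.2 CPM; SD, n = 4 and 3; log2 difference 1.51, SE 0.26, adjusted p = 0.950). Others with higher values were the sulfotransferase gene Sult1a1 (47.2 ± 14.7 and 16.6 ± 2.85 CPM; 1.39), Selenbp1 (1.57), Mt3 (2.51), Dlk2 (2.58), Chrd (1.66), Krt20 (1.70) and Fam107a (2.89, adjusted p = 0.921). Lower were Phlda1 (-1.58) and the heat shock gene Hspa1b (-1.16). Cxcl13, the chemokine that draws B cells into follicles, was at 15.4 ± 9.78 and 4.92 ± 1.57 CPM (1.85, adjusted p = 0.950). Jchain was at -1.40, Mzb1 at -1.05, Ms4a1 at -0.47, and Cd79a at -0.43. Cd8a was at 0.36, Pdcd1 at 0.29, Cd274 at -0.08, Gzmb at -0.45, Cxcl9 at 0.08, Mki67 at 0.35, Afp at -0.09, Hpd at -0.47 and Tat at 0.24 (30.3 and 45.2 CPM, so means and model differ in sign).

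Camera shifted 9 of 44 lists there, 6 up and 3 down, and 0 with an estimated correlation, where each adjusted p = 0.931 unless given. Targets of the stress factor ATF4 were lower (median -0.46, adjusted p = 5.54e-04), with Chac1 falling over the list alone (-1.0), as were plasma cell genes (-0.49, adjusted p = 0.00733) and pericentral liver genes (-0.55). Up by camera were MHC class I (0.39, adjusted p = 0.00408), MHC class II (0.44), acute phase (0.58, adjusted p = 0.00733), proliferation (0.19), mast cell (0.87) and muscle genes (3.38). Summed acute phase genes were at 4567 and 1942 CPM in Chow anti-PD-1 A1 and B1. In MASH anti-PD-1 A2 and B2 they were at 743 and 790 CPM, below every IgG section (847 to 1264 CPM). Adjusted over the list alone, the macrophage genes Cd163 (2.32) and Mrc1 (1.39) rose and the cytokine gene Il1b (-1.37) and Spp1 (-1.12) fell. With image scale as a block the ATF4 list was at -0.49 (adjusted p = 0.00154), within the larger scale at -0.57 and within the smaller at -0.50. Within the larger scale Chow IgG C1, with 171 low spots, is the 1 IgG section here, so a change of sign between scales can rest on that section. MHC class II turned from -0.44 within the larger (adjusted p = 0.00113) to 0.69 within the smaller scale (adjusted p = 0.00143). The T-cell list, not among the shifted ones over all sections, turned from -1.01 within the larger (adjusted p = 2.50e-08) to 0.57 within the smaller scale (adjusted p = 0.0163). The interferon-γ list turned from -0.72 (adjusted p = 1.50e-06) to 0.47 (adjusted p = 0.0242). Plasma cell genes were at -0.99 (adjusted p = 6.92e-04) and -0.30 (adjusted p = 0.111). Without MASH anti-PD-1 A2, MHC class II was at 0.28 (adjusted p = 0.0793) and muscle genes at 0.05 (adjusted p = 0.973). The gene count was 0 with the block, 575 without Chow anti-PD-1 A1, 158 without Chow anti-PD-1 B1 and 9 without MASH anti-PD-1 B2.

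In hepatocyte-gene-high spots proliferation genes were higher under anti-PD-1, at 482 ± 160 CPM against 261 ± 135 CPM (SD, n = 4; median 0.76, camera adjusted p = 2.11e-05; adjusted p = 0.911 with an estimated correlation). Pericentral liver genes were lower (-0.81, adjusted p = 1.75e-04; adjusted p = 0.493 with an estimated correlation). MHC class II (0.63), MHC class I (0.37), interferon-γ response (0.30, adjusted p = 0.0240), T-cell (0.27, adjusted p = 0.0295) and mast cell genes (1.53) were also up by camera. For each of these 5 lists the adjusted p was also 0.911 with an estimated correlation. Over the list alone the mast cell proteases Cma1 (2.26), Tpsb2 (2.25) and Cpa3 (2.18) rose, and Nr0b2 of bile acid control fell (-2.32). The summed mast cell level was 208 CPM in Chow anti-PD-1 A1 and at most 63.4 CPM elsewhere. Of 14907 genes 0 passed with edgeR, 620 had an unadjusted p under 0.05 and DESeq2 called 3. Values at an adjusted p of 0.922 were 1.18 for Them6 (30.3 ± 2.71 and 13.0 ± 1.31 CPM), 1.44 for Cavin3, 1.16 for Rapgef3, 1.17 for Zc3h6, and 0.95 for Pdlim2. Others were 1.56 for Ephb6, 1.46 for Prune2, 1.88 for Vegfd and -1.20 for Ugt2b36. Tat was at -1.01 (0.49 without Chow IgG C1 and 0.71 without MASH IgG C2), Hpd at -0.62, Mki67 at 0.97 (80.6 ± 35.4 and 35.9 ± 21.5 CPM), Jchain at -0.77, Cd274 at 0.05 and Cxcl13 at 0.01 (9.48 and 17.0 CPM, so means and model differ in sign). Jchain reached 369 CPM in Chow IgG C1, 152 CPM in Chow anti-PD-1 A1 and at most 76.7 CPM in any other section, so its sign can rest on single sections. The proliferation list was at 0.95 with image scale as a block, 1.66 within the larger and 0.53 within the smaller scale. In high spots its level fell from up to 2 to over 5 grid steps from low spots, from 974 to 348 CPM in Chow anti-PD-1 A1 and from 636 to 112 CPM in Chow IgG C1. High spots within 2 steps ran from 77 of 2079 in Chow IgG C1 to 874 of 971 in Chow anti-PD-1 B1. Admixture of low tissue is therefore not separated from proliferation in liver. Within the smaller scale the interferon-γ list was at 0.21 (adjusted p = 0.371). Without the shallow section MASH IgG C2, 6 lists were shifted in place of 13, and the interferon-γ list was at 0.04 (adjusted p = 0.607), the T-cell list at 0.07 (adjusted p = 0.516) and MHC class II at 0.29 (adjusted p = 0.0905).

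Within Chow, in low spots, acute phase genes were higher under anti-PD-1 than under IgG (median 1.48, camera adjusted p = 1.0e-07; adjusted p = 0.745 with an estimated correlation). Of these 9 of 12 rose over the list alone, among them Hpx (1.32), Orm1 (1.98) and Fgl1 (1.70). The summed level was 4567 CPM in Chow anti-PD-1 A1 and at most 1942 CPM elsewhere. ATF4 targets were lower (-0.52, adjusted p = 6.15e-07; adjusted p = 0.862 with an estimated correlation), and Chac1 (-1.63) and Trib3 (-1.52) fell over the list alone. No gene passed with edgeR, 502 had an unadjusted p under 0.05 and DESeq2 called 15. Values at an adjusted p of 0.992 were 1.67 for the glutathione transferase gene Gstt1 (103 ± 10.8 and 31.7 ± 5.65 CPM; SD, n = 2), 2.31 for Tmem176a, and 1.90 for Tmem176b. Others were 3.37 for Fam107a, 1.54 for Fmo1, 1.49 for Txnip, -1.57 for Mmp3, -1.43 for Cxcl14 and -1.21 for Timp1. With image scale as a block, acute phase genes were at 1.37 (adjusted p = 1.36e-06). Leaving out Chow anti-PD-1 A1 gave 783 genes and leaving out Chow anti-PD-1 B1 gave 76.

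Within MASH, in low spots, 2 anti-PD-1 sections were set against 1 IgG section, whose spread was taken from the other groups. Plasma cell genes were lower (median -0.92, camera adjusted p = 0.00566) and interferon-γ response (0.39, adjusted p = 0.00566) and MHC class I genes (0.47) were higher under anti-PD-1, each with an adjusted p = 0.905 with an estimated correlation. Jchain was at 18.6 ± 2.28 and 57.6 CPM (-1.66). No gene passed with edgeR, 291 had an unadjusted p under 0.05 and DESeq2 called 0. Values at an adjusted p of 1.0 were -1.84 for Hspa1b, -2.11 for Hsph1, both heat shock genes, -2.01 for Il1b, -1.75 for Phlda1, and -1.0 for Nab2. Others were 1.55 for Sult1a1, 1.73 for Selenbp1, 2.55 for Arrdc2, 2.0 for Sgk1, 2.42 for Fam107a and 2.31 for Cxcl13. Muscle genes were higher (median 7.60) through MASH anti-PD-1 A2, and without that section they were not (0.27, adjusted p = 0.936). With image scale as a block the plasma cell list was at -0.56 (adjusted p = 9.50e-04). Leaving out Chow anti-PD-1 A1 gave 78 genes, Chow anti-PD-1 B1 79 and MASH anti-PD-1 B2 12, which enter through the shared estimate of spread or the contrast itself.

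The difference between these antibody effects was tested as an interaction. Acute phase genes responded less in MASH than in Chow (median -1.68, camera adjusted p = 3.17e-08; adjusted p = 0.570 with an estimated correlation), and Hpx (-2.05), Apcs (-1.75), Steap4 (-1.60) and Fgl1 (-1.94) fell over the list alone. That list was at -1.67 with image scale as a block (adjusted p = 1.35e-08) and, without MASH anti-PD-1 A2, at -1.40 (adjusted p = 8.97e-07). Of 44 lists 17 were shifted, 14 up and 3 down, 7 with image scale as a block, and 0 with an estimated correlation or with fry. No gene passed with edgeR, 119 had an unadjusted p under 0.05 and DESeq2 called 2. Values at an adjusted p of 1.0 were 2.44 for Mmp3, -2.08 for Gstt1, 1.77 for Slpi, -1.76 for Acer3, -1.58 for C4bp, 1.77 for Cxcl14, 1.47 for Pla2g7, -1.65 for Gc and 1.96 for Sgk1. Leaving out Chow anti-PD-1 A1 gave 158 genes, Chow anti-PD-1 B1 39, MASH anti-PD-1 B2 5 and Chow IgG C1 1, and without MASH anti-PD-1 A2 10 lists were shifted.

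Because the series title names tertiary lymphoid structures and plasma cells, spots with B-cell and plasma cell transcripts were counted at an equal depth of 1000 UMIs. At that depth B-cell-marker spots were at 0.597 ± 0.580% of spots in MASH and 0.926 ± 0.862% in Chow sections (SD, n = 4; exact permutation p = 0.486). They were at 0.839 ± 0.788% under anti-PD-1 and 0.685 ± 0.718% under IgG (exact permutation p = 0.829). They made up 1.92% of spots in Chow anti-PD-1 B1 (95% Clopper-Pearson interval 1.49 to 2.44%), 1.37% in Chow IgG D1, 1.23% in MASH IgG D2, 0.928% in MASH anti-PD-1 B2 and at most 0.282% in the sections of the larger image scale. MASH IgG C2 had 0 of 401, which allows a share of up to 0.748% by the limit of 3 counts, and of 0.916% by the Clopper-Pearson interval. At full depth, with at least 2 B-cell UMIs, the shares ran from 0% in MASH IgG C2 and 10.4% in MASH IgG D2 to 70.3% in Chow anti-PD-1 B1, so they depend on depth. In hepatocyte-gene-high spots alone, at 1000 UMIs, the shares were 1.44% in Chow anti-PD-1 B1, 1.31% in Chow IgG D1, 0.671% in MASH IgG D2 and 0.542% in MASH anti-PD-1 B2 at median depths of 14929, 8203, 3972 and 5478 UMIs. B-cell-marker aggregates of at least 3 touching spots numbered 2 in Chow anti-PD-1 B1, 2 in MASH anti-PD-1 B2 and 1 in MASH IgG D2 (diet exact permutation p = 0.714; antibody p = 0.429).

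Plasma-cell-marker spots made up 32.0% of spots in Chow anti-PD-1 A1, 28.5% in Chow IgG C1 and 21.6% in MASH IgG D2, and from 2.0 to 8.76% in the other sections. By diet they were 9.83 ± 8.34% in MASH and 17.4 ± 14.9% in Chow sections (exact permutation p = 0.343). The difference was -24.9 points within the larger and 9.67 points within the smaller image scale. By antibody they were 13.1 ± 12.7% and 14.2 ± 12.9% (exact permutation p = 1.0). Hepatocyte-gene-high spots made up 53.5 ± 28.2% in MASH and 56.0 ± 31.4% in Chow sections (exact permutation p = 0.914). They made up 43.9 ± 20.9% under anti-PD-1 and 65.5 ± 32.2% under IgG (exact permutation p = 0.257; with permutations within image scale p = 0.0556, the smallest that design allows). Within the larger scale the antibody means were 60.0 and 93.0%, and within the smaller 27.9 and 38.1%. B-cell-marker spots by diet were 0.113 and 0.207% within the larger and 1.08 and 1.65% within the smaller scale (exact permutation p = 0.111 within scale). All of these tests are two-sided, the smallest p for 4 sections against 4 is 0.0286, and over the 8 tests of spots the lowest Benjamini-Hochberg value was 0.971. Intervals and limits cover counting error only.

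**Figure D3:**
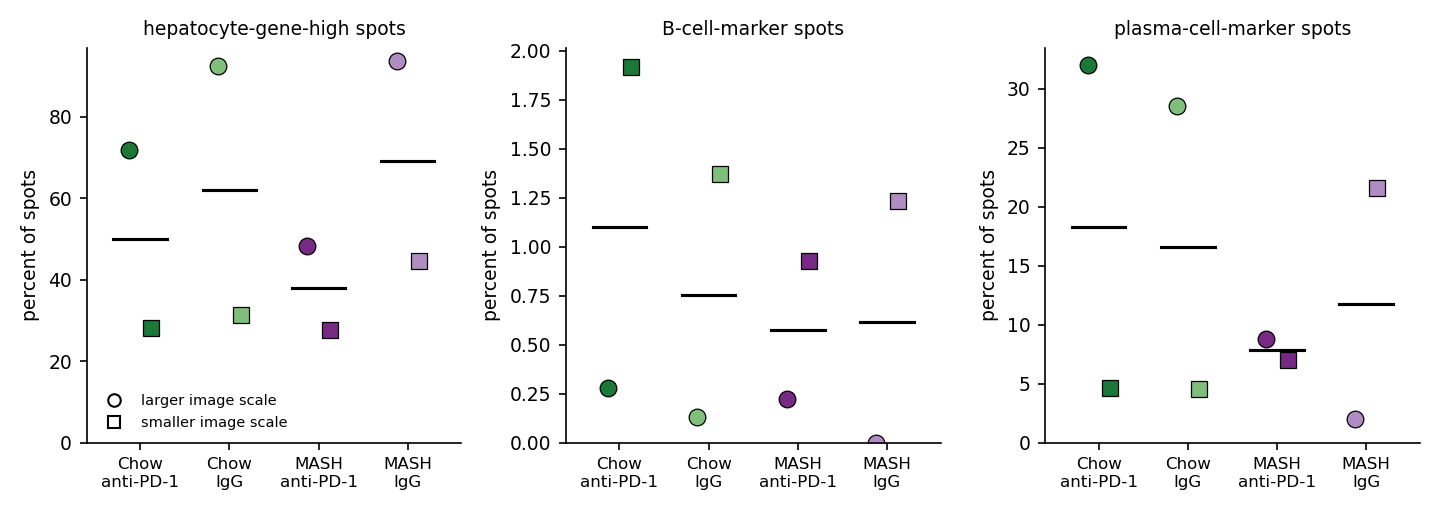
Percent of spots that are hepatocyte-gene-high, B-cell-marker and plasma-cell-marker, 1 point per section by listed group; circles are sections of the larger and squares of the smaller image scale, and bars are group means. B-cell-marker spots lay at or below 0.282% in each section of the larger scale and between 0.928 and 1.92% at the smaller scale.

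The deposited tables give Moran's I of each gene, a measure of how far neighbouring spots resemble each other, near 0 for no spatial pattern. For T-cell genes the section medians were 0.0286 ± 0.0195 in MASH against 0.110 ± 0.0743 in Chow (SD, n = 4; exact permutation p = 0.0286, the smallest possible, and 0.152 after adjustment). The median was lower in 4 of 4 MASH sections than in every Chow section. Depth differed as well, with median UMI counts per spot from 1740 to 9224.5 in MASH and from 7281 to 15640 in Chow sections, and the scores are not matched for depth. For B-cell genes the medians were 0.00980 and 0.0269 (exact permutation p = 0.0571). For the chemokine list of tertiary lymphoid structures, which also holds other genes, they were 0.0121 and 0.0351 (exact permutation p = 0.0571). Over the 8 tests of Moran's I these 3 had a Benjamini-Hochberg value of 0.152, so none passed. Plasma cell genes were at 0.0370 and 0.0711 (exact permutation p = 0.229), with Igha at 0.842 in Chow IgG C1 and Igkc at 0.423 in MASH IgG D2. By antibody the exact permutation p was 0.400 for B-cell, 0.971 for plasma cell and 0.771 for T-cell and chemokine genes. With permutations within image scale the T-cell difference by diet had p = 0.0556 in the exact test, the smallest that design allows.

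Plasma cell transcripts were also followed with distance from the border between high and low spots, a comparison chosen after the data were seen and not tested, in CPM of plain library size. In Chow IgG C1 the 11 plasma cell call genes summed to 14593 CPM in high spots up to 2 grid steps from the border and 15086 CPM over 2 to 5 steps. They summed to 1923 CPM farther into the high region and 1068 CPM farther into the low region. In MASH IgG D2 they were at 3133 CPM in low and 3493 CPM in high spots up to 2 steps from the border, against 335 and 1113 CPM over 5 steps away. MASH anti-PD-1 B2 had 1664 CPM in high spots up to 2 steps away and 196 CPM over 5 steps away, and Chow IgG D1 863 CPM in low spots up to 2 steps and 108 CPM over 5 steps away. MASH anti-PD-1 A2 had no peak there, with 446 CPM in high spots at the border and 755 CPM over 5 steps away. In Chow anti-PD-1 A1 the highest value was 2692 CPM, in high spots over 2 to 5 steps away. In Chow anti-PD-1 B1 it was 545 CPM, in high spots up to 2 steps away, against 198 CPM in low spots over 5 steps away.

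**Figure D4:**
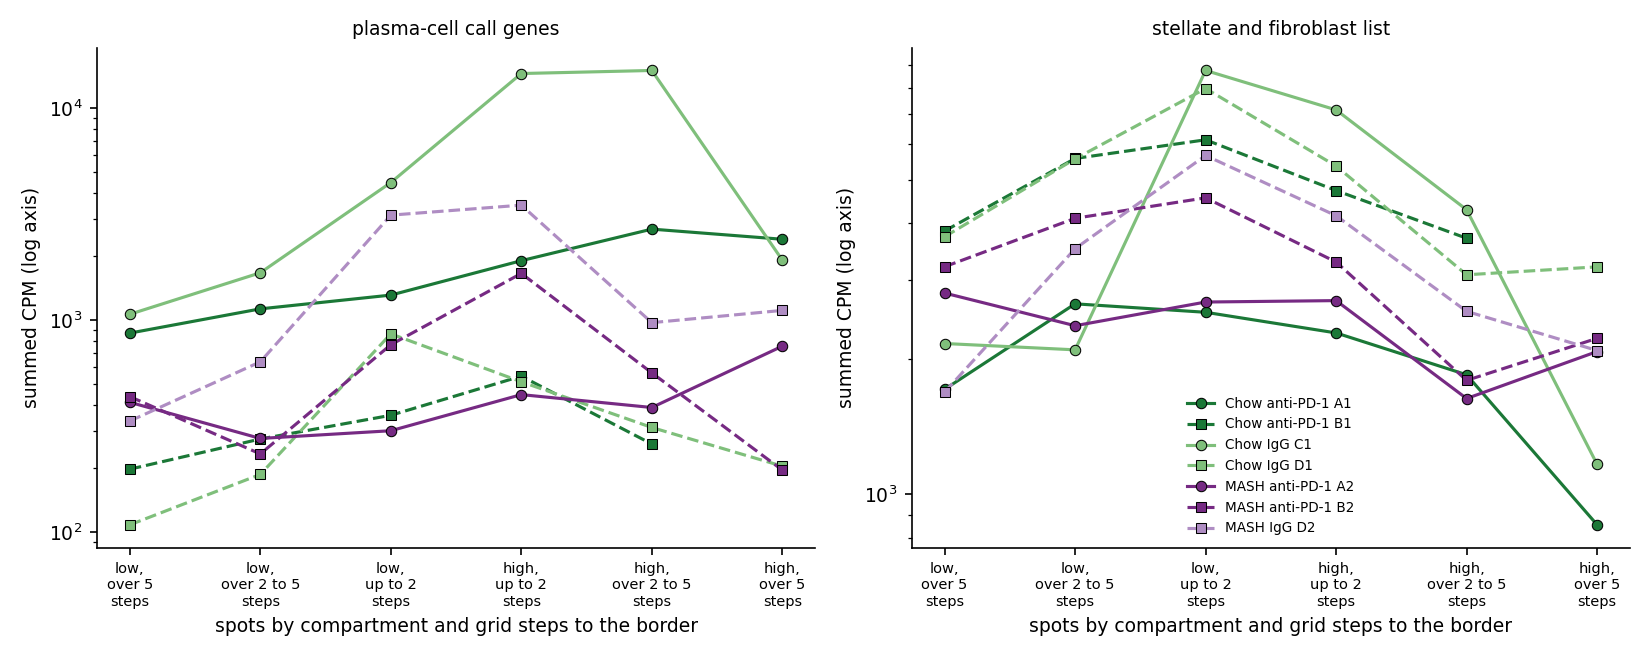
Summed CPM (log axis) of the plasma cell call genes and of the stellate cell and fibroblast list by compartment and grid steps to the nearest spot of the other compartment, 1 line per section; solid lines with circles are the larger and dashed lines with squares the smaller image scale. Bins with fewer than 20 spots are not drawn, and MASH IgG C2 is not shown; in Chow IgG C1 the fibroblast list was at 8744 CPM in low spots at the border and 1165 CPM in high spots over 5 steps away.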

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

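Tests against other splits of the sections were chosen only after the counts were seen. The tests of the file codes, of the image scales and of the muscle transcripts were written down before their results.

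Of 40 measures per section examined for a section standing far apart, 11 had one, each time the highest value. The rule flags about 5 in 100 for normal, independent values. Many of these measures are the same list in both compartments of the same sections, so that rate is no test of the 11. Chow anti-PD-1 B1 had the highest total, 54.6 M UMIs against at most 24.8 M elsewhere, the highest macrophage list in high (4597 CPM) and low spots (8245 CPM), and the highest B-cell list in low spots (208.2 CPM against at most 114 CPM). Chow anti-PD-1 A1 had the highest mast cell list in high spots, 207.5 CPM. Chow IgG C1 had the highest endothelial (1299 CPM) and pancreas and gut lists (80.4 CPM) in high spots, and Chow IgG D1 the highest neutrophil list there (267 CPM). MASH anti-PD-1 A2 had the highest skeletal muscle list in high (157 CPM) and low spots (6332 CPM) and the highest erythroid list in low spots (2358 CPM against at most 326 CPM).

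For 17 of 44 lists the effect of anti-PD-1 in low spots differed between diets by the interaction test with the preset correlation, and for 0 with an estimated correlation or with fry. The effect was lower in MASH for acute phase genes (adjusted p = 3.17e-08), the unfolded protein response (adjusted p = 4.90e-04) and hepatocyte genes (adjusted p = 0.0412), a list that defines the spots. It was higher in MASH for p53 targets (adjusted p = 3.70e-07), skeletal muscle (adjusted p = 5.73e-06), checkpoint genes (adjusted p = 5.54e-04), fibrosis (adjusted p = 0.00161), cholesterol synthesis (adjusted p = 0.00354), ATF4 targets (adjusted p = 0.00378), interferon-γ response (adjusted p = 0.00449) and lipid-associated macrophages (adjusted p = 0.00592). The same held for mast cells (adjusted p = 0.0213), T cells and erythroid cells (adjusted p = 0.0215 for both), MHC class I (adjusted p = 0.0347), hypoxia (adjusted p = 0.0402) and NRF2 targets (adjusted p = 0.0403). MASH IgG has 1 section in this test. The muscle and erythroid calls rest on MASH anti-PD-1 A2, and without it both had an adjusted p = 0.942. Of the other lists higher in MASH, mast cells, T cells, interferon-γ response, MHC class I, cholesterol synthesis and NRF2 targets had an adjusted p of 0.129 or more without it. A block for image scale gave 7 shifted lists, 6 of them among these 17. Of the 14 above that were higher in MASH, p53 targets (adjusted p = 0.0250), checkpoint genes (adjusted p = 0.00436) and fibrosis (adjusted p = 0.0273) were among them, and the other 11 were not.

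The title codes and file-name codes disagree for 6 of 8 sections, and grouping by file-name code gave 228 genes changed by diet in high spots, where the listed grouping gave 0. That is what file sets listed under the wrong sample would give, but in the file-code grouping diet coincides with image scale, so the count does not separate the 2 readings. Of 35 splits of the sections into 4 and 4, this split alone, 1 of 35, gave 485 genes in high spots. The highest other gave 0. The smallest share these splits can give is 1 of 35, and the test was chosen after the counts were seen. Chance is therefore not excluded. In low spots, without MASH IgG C2, the same division gave 0 genes, while a split that follows no label gave 1938. A technical difference between image scales should reach both compartments; over 193 genes not higher in high spots, the median difference in low spots was 0.321 of that in high spots, between the bounds of 0.25 and 0.5 set for the test, so a technical difference and one of tissue or diet cannot be told apart. A diet effect under the file codes stays open and untested. Under those codes the split by listed diet is the split by antibody, so shifts by listed diet would be shifts by antibody.

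For the listed groups the real count was 0 with edgeR, so 35 of 35 splits gave as many genes in each of the 5 comparisons by diet or antibody. A count of 0 fixes that outcome: chance is not excluded, and the splits say no more about it. The highest other split gave 485 genes in high spots and 2062 over whole sections, both times the split by image scale, with 0 genes for diet with image scale as a block. In low spots the highest was 1938, for Chow IgG D1, MASH anti-PD-1 B2 and MASH IgG D2 against the rest, 3 of the 4 sections of the smaller scale; the split by image scale itself gave 0 there. These are the highest counts among 35 splits. Whether they mark a structure of the samples that the listed groups do not follow was not tested.

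Skeletal muscle transcripts in MASH anti-PD-1 A2 are consistent with muscle tissue lying in the section: 84.4% of 87000 muscle UMIs lay in its richest 10% of spots. The share alone separates little, since sparse counts gave 59.2 to 100% in the other sections, but 685 spots of this section held at least 10 muscle UMIs and 0 spots of any other did. No biological explanation was tested.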

How the results depend on the processing

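Tests by image scale, list and Moran's I values by file-name code, and leaving out a section for list counts, shares of high spots and Moran's I were chosen only after the data were seen.

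Of 435 alternatives over 33 results, 328 were labelled the same, 39 stronger, 31 weaker, 35 reversed and 2 moved beyond the spread. For gene and list counts these labels compare the size of the count alone. The same means a count within a fixed ratio of the reported one, and direction is not compared. By file-name code, diet in high spots gave 27 lists in place of 19 and is labelled the same. Of those lists 0 had the reported direction and 14 the opposite. For section values the label follows the sign and the side of an unadjusted exact p of 0.05. Except where named, the cause was not tested.

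DESeq2 gave 9 genes for diet in high spots, 103 in low spots and 12 over whole sections, 31 and 3 for anti-PD-1 in low and high spots, 15 within Chow and 2 for the interaction, where edgeR gave 0. File-name code gave 228, 19, 4715, 63, 79 and 30 genes for diet in high, low and whole sections, anti-PD-1 in low spots, within Chow and the interaction. Within the larger scale 78 genes differed by diet in low spots, with A2 as the 1 MASH section, and 169 within MASH with only the 2 groups in the fit. Image scale, the label letter (the pairing block, diet only) and hepatocyte share as terms left the counts at 0.

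Leaving out a section gave 0 to 970 genes for diet in low spots (970 without Chow anti-PD-1 A1, 255 without Chow anti-PD-1 B1, 12 without Chow IgG D1, 14 without MASH anti-PD-1 B2), 0 to 3 over whole sections (3 without MASH anti-PD-1 B2) and 0 in high spots. It gave 0 to 575 for anti-PD-1 in low spots (575 without A1, 158 without B1, 9 without B2), 0 in high spots, 0 to 783 within Chow (783 without A1, 76 without B1), 0 to 79 within MASH (78 without A1, 79 without B1, 12 without B2) and 0 to 158 for the interaction (158 without A1, 39 without B1, 5 without B2, 1 without C1). In low spots the fit without MASH IgG D2 could not be had where it leaves the MASH IgG group empty. The 7623 genes that differ between compartments stayed between 5398 and 7961.

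Estimated correlation and fry left 0 lists in each comparison. Within the larger scale 12 lists were shifted by diet over whole sections, and 26 and 21 by anti-PD-1 in low (C1 as the 1 IgG section) and high spots; within the smaller scale 8 in high spots. With image scale as a block 3 were shifted within Chow and 7 for the interaction. By file-name code there were 10 for diet and 29 for anti-PD-1 in low spots. Without MASH IgG C2 12 lists were shifted by diet and 6 by anti-PD-1 in high spots. Without MASH anti-PD-1 A2 there were 18 for diet, 9 for anti-PD-1, 6 within Chow, 10 within MASH and 10 for the interaction.

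In percentage points, the share of high spots by diet (-2.46) was 2.82 at the doubled threshold, -43.5 by file-name code and -15.8 to 9.68 leaving out a section (2.82 without A1, 9.68 without C1, 6.19 without B2, 0.474 without D2). By antibody (-21.6) it was 2.46 by file-name code and -33.0 to -12.2 leaving out a section. B-cell-marker spots by diet (-0.330) were 0.0191 in low spots alone, 1.20 by file-name code and -0.594 to 0.00159 leaving out a section (0.00159 without B1). By antibody (0.154) they were -0.167 in low spots alone and -0.206 to 0.383 (-0.206 without B1, -0.0297 without C1, -0.0742 without C2). Plasma-cell-marker spots by diet (-7.61) were -24.9 within the larger and 9.67 within the smaller scale, and -11.9 to -2.76 leaving out a section. By antibody (-1.08) they were 0.582 at 2000 UMIs, 0.834 at 1 UMI, 7.61 by file-name code and -7.37 to 3.71 (1.74 without B1, 3.71 without C1, 0.367 without A2, 0.963 without B2, 1.39 without D2).

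Aggregates per 1000 spots by diet (0.0876) were -0.509 at 2000 UMIs, -3.54 at 1 UMI and -0.0343 to 0.233 leaving out a section (-0.0343 without B2). By antibody (0.212) they were -0.0876 by file-name code, -0.0834 at 5 spots and 0.111 to 0.310.

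Moran's I by diet: B-cell genes (-0.0171) were at 0.00753 by file-name code and -0.0209 to -0.0131 leaving out a section (-0.0209 without B2). Plasma cell genes (-0.0341) ranged from -0.0462 to -0.0112. T-cell genes (-0.0817) were at -0.0285 by file-name code, -0.0817 with image scale as a block, -0.0775 with the mean and -0.0970 to -0.0447 (unadjusted p above 0.05 without A2 -0.0839, B2 -0.0862, C2 -0.0720 or D2 -0.0845; the adjusted p of the full test was 0.152). Lymphoid chemokines (-0.0230) were at 9.75e-04 by file-name code, -0.0290 with the mean and -0.0275 to -0.0150 (-0.0275 without A1).

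By antibody, B-cell genes (0.00751) ranged from 0.00190 to 0.0134. Plasma cell genes (-0.00832) were at 0.0341 by file-name code and -0.0228 to 0.0189 (0.0189 without C1), T-cell genes (-0.0288) at 0.0817 and -0.0568 to 0.0171 (0.0171 without C1), and lymphoid chemokines (-0.00429) at 0.0230, 0.00115 with the mean and -0.0131 to 0.00681 (0.00681 without C1). Depth limits MASH IgG C2 most, with 401 spots at 1000 UMIs.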

Other observations

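No test in this part was chosen before the result was seen; the values are given without an explanation.

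Stellate cell and fibroblast genes were highest in low spots next to the border in Chow IgG C1 (8744 CPM, against 2162 CPM more than 5 steps into the low region), in Chow IgG D1 (7972 and 3734 CPM) and in MASH IgG D2 (5659 and 1686 CPM). The same held in MASH anti-PD-1 B2 (4557 and 3203 CPM). In Chow anti-PD-1 B1 they were at 6132 and 3845 CPM, and only a bin of 1 spot was higher. In Chow anti-PD-1 A1 the highest value was 2649 CPM, in low spots over 2 to 5 steps away. There the genes were at 2537 CPM at the border and 1710 CPM more than 5 steps into the low region. In MASH anti-PD-1 A2 they were at 2673 CPM at the border and 2799 CPM farther into the low region.

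In the plasma cell list, Igha had the highest Moran's I in Chow anti-PD-1 A1 (0.722), and Igkc in Chow anti-PD-1 B1 (0.310). Sdc1, which is not an immunoglobulin gene, led that list in Chow IgG D1 (0.368) and in MASH anti-PD-1 A2 (0.438). Trbc2, a constant chain of the T-cell receptor, led the T-cell list in Chow IgG C1 (0.469) and in MASH anti-PD-1 A2 (0.271). Cd72 led the B-cell list in Chow IgG C1 (0.189), and Cd79a in MASH anti-PD-1 B2 (0.113).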
